A study of Mus musculus with 8 samples.

How the data were processed

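Liver RNA of male C57BL6 mice was measured by sequencing of polyadenylated RNA in 8 libraries, with 4 libraries from mice carrying C2-AKT and 4 from control mice. Per the labels, the mice were placed on a high-fat diet at 8 weeks of age and kept on it for 10 weeks. The labels give a genotype, a title and a number from 2 to 5 for each library, and those numbers occur in both groups. Before it the titles hold another number, 2 in every control and 4 in every C2-AKT library. Whatever that number stands for cannot be told apart from the genotype. Titles carry 3 kinds of ending: no ending in control replicate 5 and C2-AKT replicate 2, "_2" in C2-AKT replicate 5 and "_1" in the other 5 libraries. The labels do not state what the endings or numbers stand for, nor that each library came from its own animal, so p-values measure the spread between these libraries.

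The deposited table lists 45777 genes by Entrez identifier and RefSeq transcript, with an estimated count, an FPKM and a TPM per library, and every value column was matched to 1 library by its title. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used with the mouse builds GRCm38 and mm10; their settings, and the strand of the library kit, are not given in the sources used here. The deposited counts are whole numbers, and how they were made from the reads is not given in the sources used here. In 180 genes with a count of 1 in a pair of libraries, the deposited FPKM of the same gene differed between those libraries by up to 119-fold. The deposited FPKM values are scaled to transcript length and library size per the file headers, and the deposited TPM values sum to between 999908 and 999971 in each library. Reads from near-identical genes can be shared out between them in such counts, so values of single members of gene families, such as Mug2, Cyp2a4, Cyp2a22, Saa1, Saa2, Mup20, Mt1, Mt2, Hspa1b and Amy2a5, are uncertain. Coordinates are those of the RefSeq annotation of GRCm38.p6, the same build, and 45679 of the 45777 identifiers were matched to it.

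Total counts ranged from 51.4 to 63.8 M per library (M for mega, the unit of CPM). Genes were kept with edgeR's filterByExpr at its default settings, which left 15686 genes, and library sizes were scaled by TMM. Differences between C2-AKT and control libraries were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used, since the labels do not say that the shared numbers pair animals. Each standard error is the log2 fold change divided by the square root of the F statistic, and intervals are 95% intervals. Levels per library are CPM after TMM scaling, except the pancreatic transcripts, which are CPM of all counts because most of them were removed by the filter. Shares of counts carry exact Clopper-Pearson 95% intervals, and the limit for a gene with no count is 3 counts in that library. Both cover counting error only.

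The gene lists were fixed before the data were examined: 26 pathway lists and 13 lists of cell type markers, 39 in all. Each was tested with limma's camera on log2 CPM with a preset correlation of 0.01, two-sided and adjusted over the 39 lists, and again with camera with an estimated correlation and with limma's fry. The mean log2 CPM of each list was also compared between groups by an exact permutation test over the 70 assignments of 8 libraries, two-sided, whose smallest possible p is 0.0286. Counts of members past 0.05 are given over all genes tested and adjusted over the list alone.

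The genes named in the text follow a rule written before the data were examined. Akt1, Akt2 and Alb are among the genes it always names, and not every gene it selects is printed here. Called genes with a mean of at least 1 CPM and no overlap between groups follow, leaving out symbols made of Gm and a number, Rik and LOC symbols and antigen receptor segments, and are filled up in order of unadjusted p to 20 genes. From each list, up to 4 members with the smallest unadjusted p are named, as values only where no member was called. Clock genes past the threshold would also be named, and there were 0 of them. A gene named outside this rule is said to be chosen after its values were seen.

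Alternatives chosen beforehand were DESeq2 size factors, upper-quartile factors, library totals alone, library sizes without the 20 most abundant genes, no count filter, a mean of at least 1 CPM, DESeq2's Wald test, limma-voom, limma on log2(FPKM + 1), log2(TPM + 1) and log2(FPKM + 0.1) with a mean of at least 1, a replicate block, and each library left out in turn. Further alternatives were added after seeing the data: the title ending as a term, only the libraries whose titles end in "_1", and the title ending as a term without C2-AKT replicate 5. The exact permutation test of lists was added as well. DESeq2 gave an adjusted p for 14422 genes. A further 9929 genes had a p-value but no adjusted p. These were left out of its counts, as was any gene without a p-value.

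The gene test was checked on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed among 15460 tested. It recovered 74 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, and 13 of its 186 calls were false. Camera called the 1 raised list and 0 of the other 19 simulated lists. Genes were drawn independently there, so this check could not show how camera behaves where members of a list vary together. In the real data the estimated correlation was 0.63 for the cholesterol synthesis list. Within each group, all pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom of at least 44.9), so no library was counted as a copy of another. Transcript GC content and length were taken from the GENCODE M21 transcripts, averaged per gene, for 14620 of the 15686 genes (93.2%). Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package (1.17.8) and, for the plots, Python with matplotlib 3.10.9.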

Results

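Expression was measured in the livers of male mice that express C2-AKT in hepatocytes and of control mice, all fed a high-fat diet. AKT is the protein kinase that carries the insulin signal from phosphoinositide 3-kinase to glucose and lipid metabolism. C2-AKT is a modified AKT whose coding sequence was placed at the ROSA26 locus and switched on by Cre recombinase under the albumin promoter, which is active in hepatocytes. The labels do not state which AKT isoform or which species' sequence it carries, nor whether control mice carried Cre. The study asked what C2-AKT does in the liver of obese mice, and the single comparison its design gives is C2-AKT (n = 4) against control (n = 4). The estimated counts per library summed to between 51.4 M (control replicate 3) and 63.8 M (C2-AKT replicate 4).

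C2-AKT replicate 5 contained transcripts of the exocrine and endocrine pancreas. The 10 genes of the acinar cell list took 8.80% of its counts (95% interval 8.80% to 8.81%), against 0.000747% to 0.00266% in the other 7 libraries. The amylase gene Amy2a5 reached 16981 CPM of all counts in that library, the lipase gene Pnlip 12981 and the insulin gene Ins2 32.5. Ins2 had no count in the other 7 libraries, which allows up to 0.0583 CPM. In C2-AKT replicate 4, Amy2a5 stood at 3.53 and Pnlip at 2.99 CPM. Genes removed by the count filter held 17.2% of the counts of C2-AKT replicate 5 and at most 0.0478% in the other libraries, and its first principal component score was 57.2, against -37.1 to 8.03 in the others. The 2 libraries whose titles carry no ending, control replicate 5 and C2-AKT replicate 2, had the lowest scores on that component (-37.1 and -26.7), which held 27.8% of the variance.

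**Figure D1:**
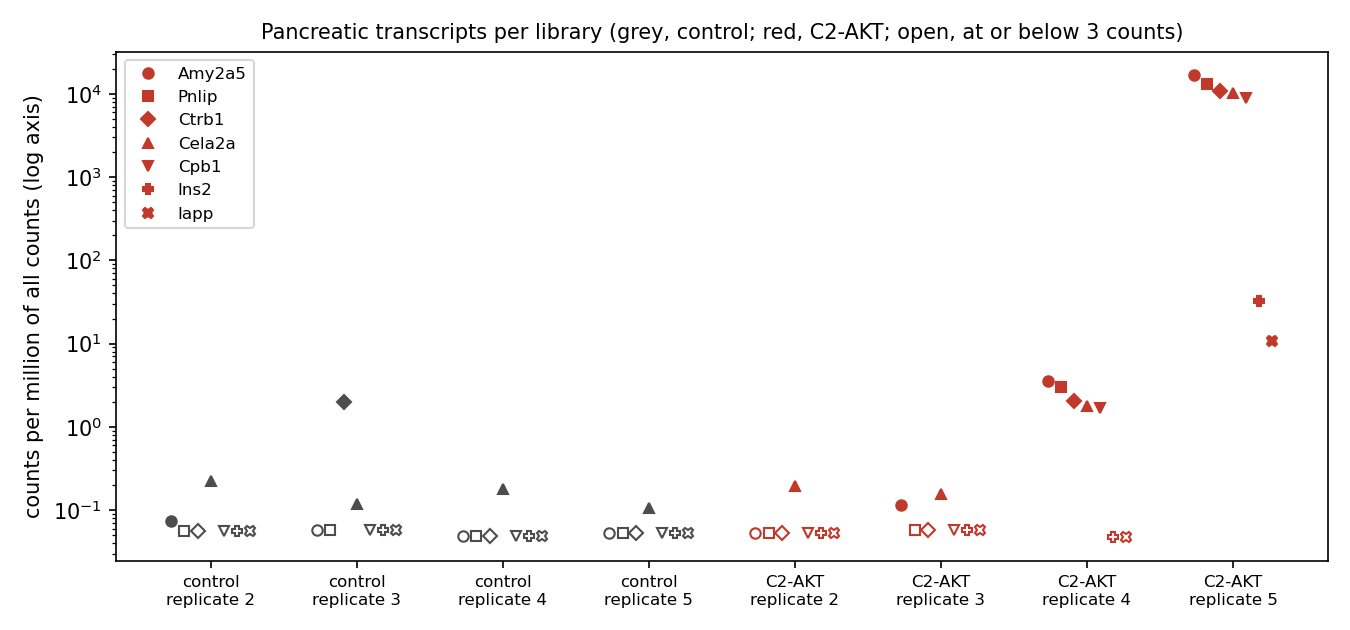
Pancreatic transcripts in each of the 8 libraries, in CPM of all counts on a log axis, for 5 acinar and 2 islet genes. Grey points are control and red points C2-AKT libraries, and open points, drawn at the limit of 3 counts, had no count above it. C2-AKT replicate 5 lies far above the other libraries for the acinar genes, with Amy2a5 at 16981, and C2-AKT replicate 4 holds Amy2a5 at 3.53.

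In C2-AKT livers, 4 genes were lower and 0 were higher than in control livers by edgeR's quasi-likelihood test. The lower genes were the murinoglobulin gene Mug2, its neighbouring pseudogene Gm10319, the pro-apoptotic BH3 gene Bid and the serine/threonine kinase gene Pim1. Genes of cholesterol synthesis were higher as a group and acute phase and lipid droplet genes lower as groups, against other genes under a preset correlation, but no list passed with an estimated correlation. Akt1 and Akt2 did not pass, nor did the FOXO-responsive list in directional tests, and gluconeogenesis passed only in some alternatives. DESeq2 called 29 genes higher and 27 lower, limma-voom 0 and 3, and 805 of the 15686 genes had an unadjusted p below 0.05 in edgeR, where chance alone gives 784.

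The endogenous transcript of the ROSA26 locus, the noncoding RNA Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077244, GRCm38), was measured at 6.12 ± 1.55 CPM (SD, n = 4) in control and 0.422 ± 0.331 CPM in C2-AKT livers. All 4 C2-AKT libraries, including C2-AKT replicate 4 with no count (a limit of 0.0470 CPM), lay below all 4 control libraries, which ranged from 4.73 to 7.96 CPM. Its log2 fold change was -3.90 ± 0.65 (SE), with an edgeR adjusted p of 0.181. It passed with DESeq2 (adjusted p = 0.0271), with limma on the deposited FPKM + 1 (adjusted p = 0.000926) and without C2-AKT replicate 4 (edgeR adjusted p = 0.0150), over a range of 0.000926 to 0.647 across the alternatives. Akt1 stood at 41.4 ± 7.43 CPM in control and 42.7 ± 10.1 CPM in C2-AKT livers (log2 fold change 0.04, 95% interval -0.37 to 0.45). The log2 fold change was -0.14 for Akt2 (-0.52 to 0.23), and ranged from -0.27 to -0.02 across the alternatives. Both genes had an edgeR adjusted p of 0.9999, and the sign for Akt1 turned in some alternatives. Whether reads of the construct were counted at a mouse Akt gene is not stated in the sources used here. Alb, whose promoter drives Cre, stood at 54614 ± 10588 CPM in control and 63875 ± 5450 CPM in C2-AKT livers (log2 fold change 0.23, -0.10 to 0.55).

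Gm10319, named after its values were seen, fell by 2.11 ± 0.11 on the log2 scale, from 50.6 ± 4.22 to 11.7 ± 1.42 CPM (SD, n = 4; edgeR adjusted p = 6.41e-05). Mug2, which encodes a secreted protease inhibitor of the alpha-2-macroglobulin family, fell by 2.12 ± 0.21, from 917 ± 117 to 212 ± 61.4 CPM (edgeR adjusted p = 0.0106). Bid fell by 1.70 ± 0.18, from 13.0 ± 2.00 to 4.01 ± 0.869 CPM (edgeR adjusted p = 0.0135). Pim1 fell by 1.38 ± 0.17, from 18.3 ± 3.86 to 7.0 ± 1.22 CPM (edgeR adjusted p = 0.0462). For each of these genes the 4 C2-AKT libraries lay below the 4 control libraries, an arrangement found in one direction or the other in 2.98% of all genes tested, where chance gives 2.86%. Without control replicate 2, Gm10319 alone was called (Mug2 adjusted p = 0.0706, Bid 0.0801, Pim1 0.0998). Without C2-AKT replicate 5, Bid (0.0564) and Pim1 (0.110) were not called. That fit called Scara5, named after its values were seen, as lower beside Mug2 and Gm10319. Scara5 was not called with all libraries, but also with the title ending as a term and among titles ending in "_1". Bid was also not called with a replicate block. Without C2-AKT replicate 2, 1 gene was higher and 16 were lower. Many of these lower genes were copies of the Mup family, such as Mup7, Mup12 and Mup13, between which reads can be shared out. Without C2-AKT replicate 3, 3 genes were higher, among them Fdft1 and Msmo1. Leaving out control replicate 4, control replicate 5 or C2-AKT replicate 4 gave 1 higher gene each. Between the 2 libraries with no title ending and the 5 ending in "_1", 1616 genes differed with genotype as a term in edgeR. Among the libraries ending in "_1" alone, 3 control and 2 C2-AKT, 0 genes were higher and 17 lower in C2-AKT livers, with 1265 at an unadjusted p below 0.05. Many of those 17 genes were Mup copies as well. With the ending as a term, which takes C2-AKT replicate 5 out of the comparison because it alone ends in "_2", 1 was higher and 5 were lower. In each of these fits, 3 of the 4 called genes were called.

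**Figure D2:**
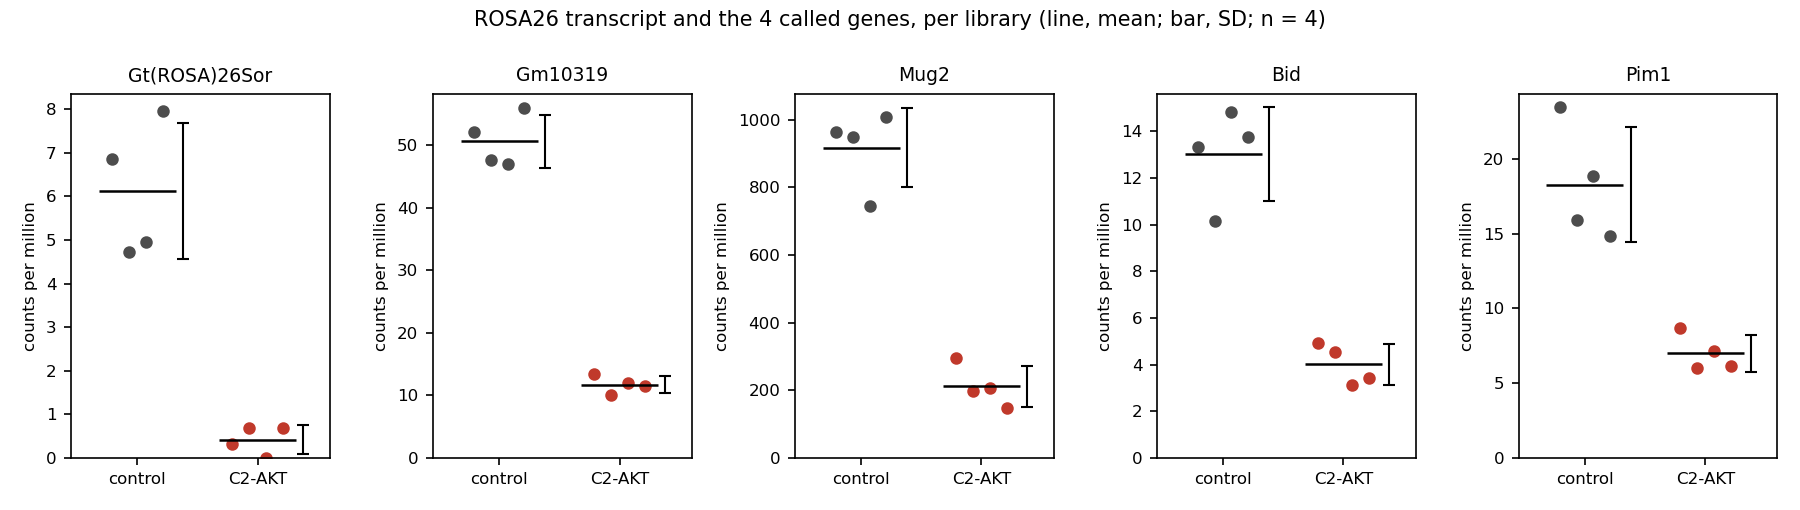
CPM of Gt(ROSA)26Sor and of the 4 called genes in each library, in control (grey) and C2-AKT (red) livers, with the group mean as a line and the SD as a bar (n = 4 per group). The groups do not overlap for any of the 5 genes, and Mug2 has a mean of 917 in control and 212 in C2-AKT livers.

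Bid, Mug2 and Gm10319 lie on chromosome 6, at 7.83, 8.94 and 9.07 Mb from the start of Gt(ROSA)26Sor, and Pim1 lies on chromosome 17. Murinoglobulin genes are near-identical copies whose reads can be shared out between them, so their single values are uncertain. Mug1, the most abundant copy and also named after its values were seen, stood at 5237 ± 331 CPM in control and 5577 ± 1670 CPM in C2-AKT livers (log2 fold change 0.09 ± 0.19), and the pseudogene Mug-ps1 had a log2 fold change of -0.99 ± 0.18 (edgeR adjusted p = 0.273). Mug-ps1 passed edgeR without C2-AKT replicate 2 (0.00656) and among titles ending in "_1" (0.0337), and passed DESeq2 (0.000194). The sum of Mug1, Mug2, Mug-ps1, Mug4-ps and Gm10319 was 6517 ± 455 CPM in control and 5999 ± 1794 CPM in C2-AKT livers (exact permutation p = 0.6, two-sided). Among genes starting within 20 Mb of Gt(ROSA)26Sor, 15 of 234 had an unadjusted p below 0.01 (6.41%), against 178 of 15421 elsewhere (1.15%; Fisher's exact p = 2.11e-07, across genes, which are not independent). Of these 15 genes, 13 had a negative log2 fold change. All 15 lay among the 194 genes at higher coordinates than the locus and 0 among the 40 at lower coordinates, a difference between the sides that did not pass (Fisher's exact p = 0.0807).

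**Figure D3:**
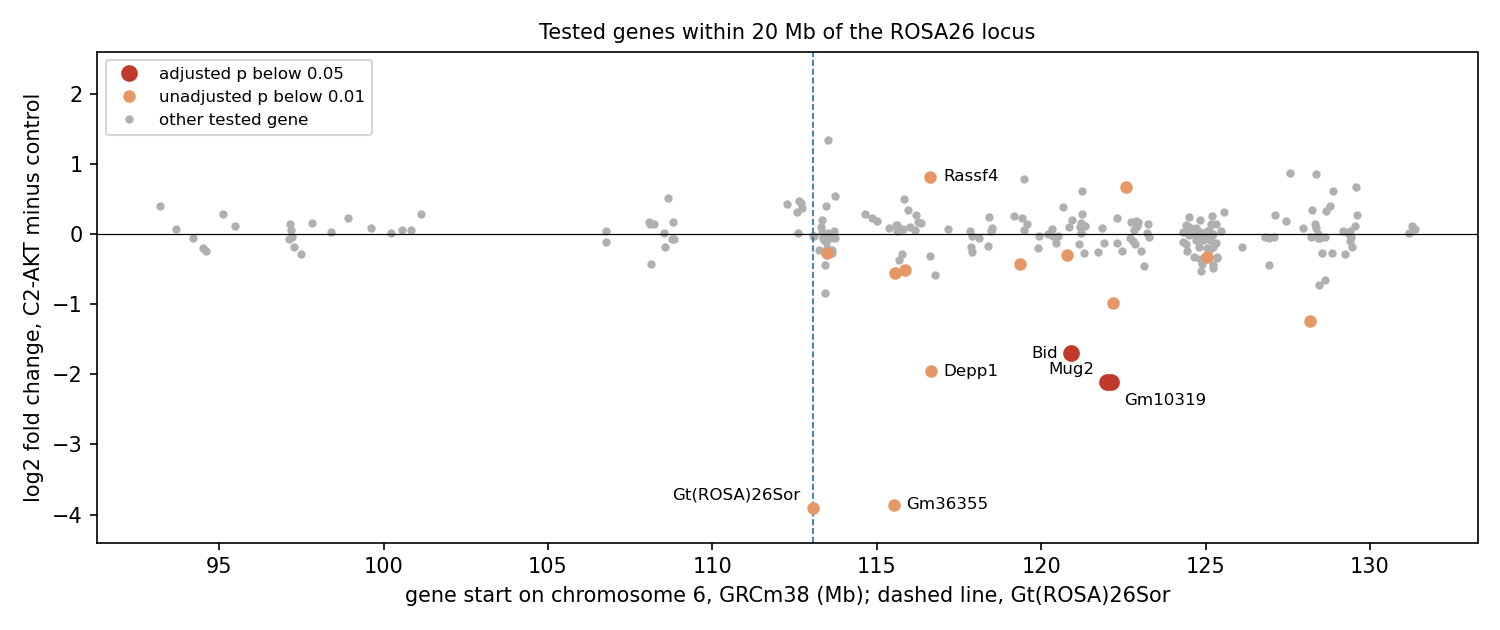
Log2 fold change (C2-AKT minus control) of each tested gene against its start on chromosome 6 in Mb, within 20 Mb of Gt(ROSA)26Sor, which the dashed line marks. Dark red points passed an edgeR adjusted p of 0.05, orange points an unadjusted p of 0.01 and grey points neither; Bid, Mug2 and Gm10319 lie between 7.83 and 9.07 Mb from the locus.

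The other genes with the smallest unadjusted p did not pass. Higher values in all 4 C2-AKT libraries were measured for Abcd2, a peroxisomal transporter of very long-chain fatty acids (28.8 ± 2.96 CPM in control, 47.4 ± 3.09 CPM in C2-AKT livers; log2 fold change 0.72 ± 0.10, edgeR adjusted p = 0.0738), and for Ccn2, a secreted matricellular protein (1.71 ± 0.537 and 5.88 ± 1.55 CPM; 1.78 ± 0.26, edgeR adjusted p = 0.0830). Lower values in all 4 were measured for Gadd45a, a growth arrest gene (5.82 ± 0.496 and 2.54 ± 0.496 CPM; -1.19 ± 0.16, edgeR adjusted p = 0.0754). The log2 fold changes of Akr1d1, Cyp2a22, Dnajb1, Hsd17b7, Gas2, Rassf4 and Hspa1b ranged from 0.59 for Akr1d1 to 1.32 for Cyp2a22, and those of Erdr1, Fbf1, Depp1 and Plin4 from -1.96 for Depp1 to -0.87 for Plin4, with no overlap between groups and edgeR adjusted p values of 0.136 to 0.289. Rassf4 and Depp1 lie on chromosome 6 within the 20 Mb around Gt(ROSA)26Sor, and Depp1 (116650684 to 116652847) lies inside the interval of Rassf4 (116633008 to 116673836), so their values are uncertain where reads were not counted by strand. For Depp1, control replicate 2 stood at 44.7 CPM and the other control libraries at 15.4 to 18.0 CPM. DESeq2 called each of these 14 genes. In edgeR, Abcd2 passed without control replicate 5 (adjusted p = 0.0478) and with library sizes that leave out the 20 most abundant genes (0.0392), and Cyp2a22 passed without C2-AKT replicate 2 (0.0368). Plin4 passed without control replicate 5 (0.0348) and among titles ending in "_1" (0.0415), and Akr1d1 with the title ending as a term (0.0397). Gadd45a passed limma on log2(FPKM + 1) (0.0342) and log2(FPKM + 0.1) (0.0376).

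The 25 genes of cholesterol synthesis and its regulation all had a higher mean in C2-AKT livers, with a median log2 fold change of 0.90 and camera adjusted p = 1.76e-22, and adjusted p = 0.318 with an estimated correlation. Adjusted over the list alone, 19 of the 25 passed in edgeR, and over all genes tested 0 passed. Over all genes, DESeq2 called members of the list, Fdft1 and Hsd17b7 among them, and edgeR called Fdft1 and Msmo1 among others without C2-AKT replicate 3. Hsd17b7, which reduces a keto group of the sterol ring, had a log2 fold change of 0.97 ± 0.18, Fdft1, the squalene synthase, 0.98 ± 0.21 and Msmo1, a sterol C4 oxidase, 1.75 ± 0.41. The mean log2 CPM of the list was 4.65 ± 0.30 in control and 5.61 ± 0.60 in C2-AKT livers (exact permutation p = 0.0857). C2-AKT replicate 3, at 4.81, lay within the control range of 4.28 to 4.95.

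Fatty acid synthesis genes were higher as a group by a smaller amount (median log2 fold change 0.17, 16 of 25 higher, camera adjusted p = 0.00683, and adjusted p = 0.721 with an estimated correlation). Adjusted over the list alone, 0 of its 25 members passed in edgeR, as over all genes. Fasn, the fatty acid synthase, had the smallest unadjusted p of the list, at 0.0247. It stood at 97.9 ± 44.2 CPM in control and 192 ± 83.7 CPM in C2-AKT livers, and the log2 fold changes of Acss2, Mid1ip1 and Fads1 were 0.25, 0.77 and 0.59. The list did not pass without control replicate 5 (camera adjusted p = 0.327), one of the 2 libraries with no title ending. Its median was 0.08 without C2-AKT replicate 4 (0.0469) and 0.26 without C2-AKT replicate 2 (0.000190). Fatty acid oxidation and ketogenesis genes did not differ as a group (median 0.03, camera adjusted p = 0.364).

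**Figure D4:**
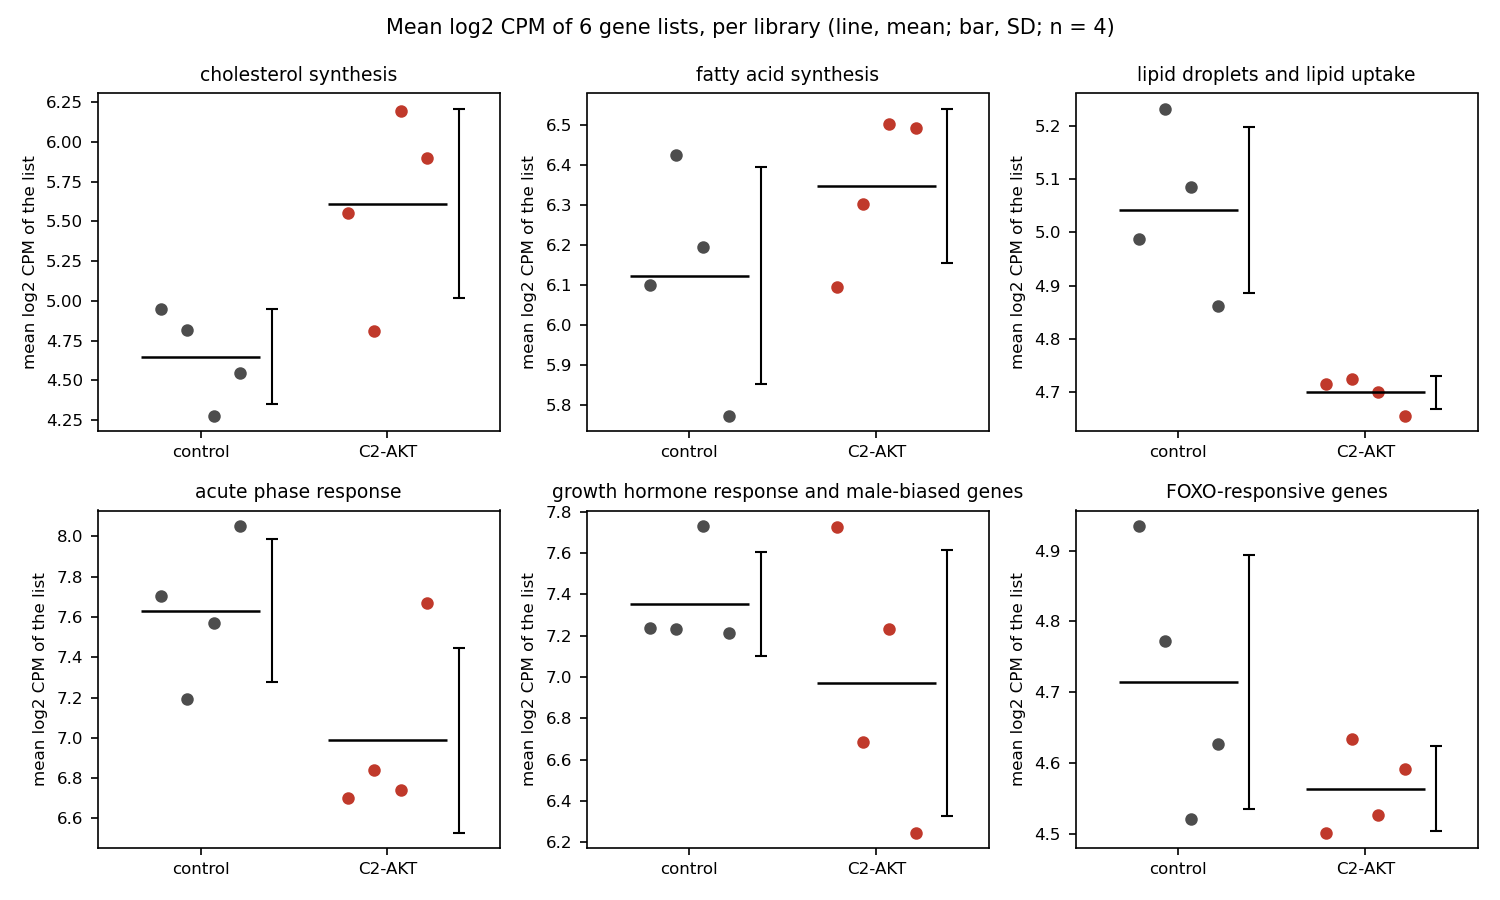
Mean log2 CPM of 6 gene lists in each library, in control (grey) and C2-AKT (red) livers, with the group mean as a line and the SD as a bar (n = 4 per group). The C2-AKT libraries lie below all control libraries for lipid droplets and lipid uptake, at 4.70 ± 0.03 against 5.04 ± 0.16, and the groups overlap for the other 5 lists.

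Genes of lipid droplets and lipid uptake were lower as a group (18 of 21 lower, median log2 fold change -0.22, camera adjusted p = 0.000929, and adjusted p = 0.314 with an estimated correlation). The list mean was lower in all 4 C2-AKT libraries than in all 4 control libraries, at 4.70 ± 0.03 against 5.04 ± 0.16 log2 CPM (exact permutation p = 0.0286, the smallest possible; adjusted over the 39 lists 0.371). Adjusted over the list alone, 3 members passed, the droplet coat gene Plin4 (65.2 ± 16.0 and 35.8 ± 3.27 CPM, log2 fold change -0.87 ± 0.17), the droplet fusion gene Cidea (6.03 ± 4.86 and 0.548 ± 0.508 CPM, -3.44 ± 0.75) and, in the opposite direction, the lipoprotein receptor gene Vldlr (4.28 ± 1.28 and 8.02 ± 1.98 CPM, 0.91 ± 0.25). Over all genes 0 passed in edgeR with all libraries, Plin4 passed without control replicate 5 (adjusted p = 0.0348) and among titles ending in "_1" (0.0415), and DESeq2 called Plin4 and Cidea. Fitm1 had a log2 fold change of -0.39. The adipocyte list, of which 3 of 8 genes were measured, was lower as well (median -1.33, camera adjusted p = 0.0118, and adjusted p = 0.393 with an estimated correlation), and Cidea, which both lists hold, was its only member past the threshold adjusted over the list alone. Its other members were Cfd, with a log2 fold change of -1.33, and Adrb3, with 0.02. The adipocyte call ended without C2-AKT replicate 5 (camera adjusted p = 0.0529) and without control replicate 5 (0.0570), and with the title ending as a term (0.0536).

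Acute phase genes were lower as a group in C2-AKT livers (24 of 25 lower, median log2 fold change -0.46, camera adjusted p = 3.39e-09, and adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone, 4 members passed: the metallothionein genes Mt1 (26 ± 6.14 and 12.4 ± 4.11 CPM, log2 fold change -1.07 ± 0.24) and Mt2 (-1.52 ± 0.36) and the serum amyloid genes Saa2 (486 ± 390 and 83.7 ± 51.6 CPM, -2.54 ± 0.64) and Saa1 (-2.01 ± 0.56). None of the 25 passed over all genes tested in edgeR, and DESeq2 called Mt1 and Mt2. The list mean was 7.63 ± 0.35 log2 CPM in control and 6.99 ± 0.46 in C2-AKT livers (exact permutation p = 0.0857). C2-AKT replicate 5, the library with pancreatic transcripts, stood at 7.67, and the other 3 C2-AKT libraries at 6.70 to 6.84; without it the median was -0.81. Control replicate 5 had the highest list mean (8.05), and without it the median was -0.29 (camera adjusted p = 0.000576). Inflammatory cytokine and adhesion genes (median 0.15, camera adjusted p = 0.372) and interferon response genes (-0.01, 0.975) did not differ as groups, and Cxcl9, of the cytokine list, had a log2 fold change of 0.79. The mean over members of the cytokine list was -0.03, of the opposite sign to its median.

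Genes of glucose metabolism did not pass as groups in camera with all libraries. The 19 FOXO-responsive genes, which AKT restrains through FOXO transcription factors, had a median log2 fold change of 0.04 and a mean of -0.17, of opposite signs (camera adjusted p = 0.372), with 11 higher and 8 lower. Of these, Gadd45a passed adjusted over the list alone, and Bcl6, Igfbp1 and Irs2 had log2 fold changes of -1.61, -0.82 and -0.57. Fry's mixed test, which lets members change in either direction, gave the FOXO-responsive list an unadjusted p of 3.89e-05. The mixed test was not adjusted over the lists. G6pc, the catalytic subunit of glucose-6-phosphatase, stood at 150 ± 65.0 CPM in control and 235 ± 59.5 CPM in C2-AKT livers, with an unadjusted p of 0.0478 and an edgeR adjusted p of 0.959. The gluconeogenesis list, which also holds G6pc, had a median of 0.08 (camera adjusted p = 0.0932). It passed in the positive direction without control replicate 3 (0.0171) or C2-AKT replicate 5 (0.0447) and with the title ending as a term (0.0392). The median was 0.09 for glycogen metabolism (0.0932), 0.04 for glycolysis and glucose uptake (0.619) and 0.05 for insulin and AKT signalling components (0.372). In these 4 lists the members with the smallest unadjusted p had log2 fold changes of 0.28 (Ppargc1a), 0.41 (Ppp1r3b), 0.42 (Pklr) and 0.38 (Pik3cb).

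Bile acid synthesis and transport genes did not differ as a group (median 0.05, camera adjusted p = 0.266), but passed, higher, without C2-AKT replicate 5 (0.00746) and with the title ending as a term (0.0120). Adjusted over the list alone, 3 of its 22 members passed: Akr1d1, a steroid reductase of bile acid synthesis (136 ± 4.57 and 204 ± 15.9 CPM, log2 fold change 0.59 ± 0.09), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (57.0 ± 14.7 and 138 ± 59.9 CPM, 1.27 ± 0.31), and Nr0b2, a nuclear receptor that represses Cyp7a1 (25.1 ± 5.32 and 12.3 ± 4.79 CPM, -1.03 ± 0.30). Over all genes, DESeq2 called Akr1d1 and Cyp7a1. Fry's mixed test gave the bile acid list an unadjusted p of 0.000303. Xenobiotic metabolism (median -0.04, camera adjusted p = 0.927), NRF2 targets (0.05, 0.372), hepatokines (-0.07, 0.364) and endoplasmic reticulum stress genes (-0.04, 0.628) did not pass with all libraries. NRF2 targets passed, higher, without C2-AKT replicate 2 (0.0408). Their members with the smallest unadjusted p were Ugt1a9 (log2 fold change 0.42), Osgin1 (-0.76), Hamp, the iron hormone hepcidin (-0.87), and Trib3 (-0.75). The mean of the stress list was 0.30, of the opposite sign to its median, and the list passed in the negative direction without C2-AKT replicate 5 (camera adjusted p = 0.0320, median -0.17) and with the title ending as a term (0.0234).

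Growth hormone-responsive and male-biased genes were lower (14 of 19 lower, median log2 fold change -0.31, camera adjusted p = 0.0159, and adjusted p = 0.803 with an estimated correlation) and female-biased liver genes higher (10 of 12 higher, median 0.89, camera adjusted p = 0.00446, and adjusted p = 0.608 with an estimated correlation). All mice were male. Of the male-biased list 0 members passed in edgeR adjusted over the list alone, and Cyp4a12a, Mup20, Cyp4a12b and Cyp7b1 had log2 fold changes of -0.82, -0.58, -0.84 and -0.79 with unadjusted p values of 0.0511 to 0.0804. Of the female-biased list, Cyp2a22 (12.7 ± 1.6 and 31.7 ± 11.3 CPM, 1.32 ± 0.22) and Cyp2a4 (0.97 ± 0.26) passed adjusted over the list alone. Over all genes 0 passed in edgeR with all libraries, Cyp2a22 passed without C2-AKT replicate 2 (adjusted p = 0.0368), and DESeq2 called Cyp2a22. Without C2-AKT replicate 3 the mean over the female-biased list was 0.28, against 0.63 with all libraries. The male-biased call ended without C2-AKT replicate 5 (camera adjusted p = 0.437), control replicate 4 (0.191), C2-AKT replicate 3 (0.173) or control replicate 5 (0.0570), and with the title ending as a term (0.466). The median of the male-biased list was -0.13 without C2-AKT replicate 5, -0.15 without control replicate 4 and -0.61 without C2-AKT replicate 2 (3.79e-06). Periportal (median 0.08, 0.550) and pericentral (0.0027, 0.749) hepatocyte genes did not pass with all libraries. The periportal list passed in the positive direction without C2-AKT replicate 5 (camera adjusted p = 0.0191, median 0.14) and with the title ending as a term (0.0111, median 0.17).

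Among the marker lists of cell types, B and plasma cell genes were higher (8 of 9 higher, median 0.38, camera adjusted p = 0.0104, and adjusted p = 0.318 with an estimated correlation), with low levels, such as Igkc at 2.42 ± 0.525 CPM in control and 3.15 ± 0.586 CPM in C2-AKT livers. Adjusted over the list alone 0 members passed in edgeR, and the call ended without C2-AKT replicate 2 (camera adjusted p = 0.0741), C2-AKT replicate 5 (0.0529) or control replicate 5 (0.0570). Hepatocyte markers had a median of 0.01 (camera adjusted p = 0.927). Camera adjusted p values were 0.265 for Kupffer cell, 0.372 for monocyte, 0.0771 for neutrophil, 0.129 for T and NK cell, 0.176 for sinusoidal endothelial, 0.266 for stellate, 0.969 for cholangiocyte, 0.372 for erythroid, 0.946 for skeletal muscle and 0.189 for pancreatic acinar markers. Without C2-AKT replicate 5 the T and NK cell (0.0111) and neutrophil (0.0191) lists passed, with medians of 0.56 and -0.45. The neutrophil list also passed, lower, without control replicate 3 (0.0139), control replicate 4 (0.0478) or C2-AKT replicate 4 (0.0481). Without control replicate 4 the Kupffer cell list passed, lower (0.0219), and the stellate list, higher (0.0219). Without control replicate 2 the sinusoidal endothelial (0.0386) and erythroid (0.00111) lists passed, higher, and without C2-AKT replicate 3 the pancreatic acinar list (0.0436). With the title ending as a term the T and NK cell (0.0140), sinusoidal endothelial (0.0439) and stellate (0.0449) lists passed, higher, and the neutrophil list (0.0280), lower. Extracellular matrix genes were higher as a group (16 of 27 higher, median 0.17, camera adjusted p = 0.00434, and adjusted p = 0.721 with an estimated correlation), and Ccn2 alone passed adjusted over the list alone. That call ended without control replicate 5 (camera adjusted p = 0.493, median 0.0087). The median was 0.033 without control replicate 2, 0.30 without control replicate 4, 0.10 without C2-AKT replicate 2, 0.11 without C2-AKT replicate 3 and 0.09 without C2-AKT replicate 4.

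Circadian clock genes were higher as a group (13 of 19 higher, median 0.10, camera adjusted p = 0.0159, and adjusted p = 0.318 with an estimated correlation), and 0 passed in edgeR adjusted over the list alone. Per1, a period gene, stood at 8.35 ± 5.31 CPM in control and 21.0 ± 7.73 CPM in C2-AKT livers, and Bhlhe40 had a log2 fold change of 0.51. The call ended without control replicate 5 (camera adjusted p = 0.0869, median 0.055) or C2-AKT replicate 3 (0.0856), and the labels do not give the time of killing. Cytosolic ribosomal protein genes had 67 of 79 members lower by a small amount (median -0.05, camera adjusted p = 0.0362, and adjusted p = 0.865 with an estimated correlation), and the call ended without control replicate 4 (0.229), control replicate 5 (0.886), C2-AKT replicate 2 (0.0602), C2-AKT replicate 3 (0.303) or C2-AKT replicate 4 (0.983). Its median was -0.0027 without control replicate 5, -0.0028 without C2-AKT replicate 4, -0.10 without control replicate 3 and -0.13 without C2-AKT replicate 5. Cell cycle genes (median 0.24, camera adjusted p = 0.124) and mitochondrial respiratory chain genes (-0.04, 0.145) did not pass with all libraries. The respiratory chain list passed, lower, without control replicate 3 (0.00977), C2-AKT replicate 2 (0.0408) or C2-AKT replicate 3 (0.00678), and the cell cycle list passed, higher, without C2-AKT replicate 2 (4.53e-05). Without C2-AKT replicate 5 the cell cycle median fell to 0.059 (camera adjusted p = 0.870). Of the 39 lists 11 passed camera with the preset correlation, 6 higher and 5 lower. After adjustment 0 passed with an estimated correlation, with fry's directional test or with the exact permutation test, whose smallest adjusted p was 0.371. In the exact test, 3 lists reached the smallest unadjusted p of 0.0286, with no overlap of list means between groups. These were lipid droplets and lipid uptake (lower), adipocyte (lower) and circadian clock (higher, 4.36 ± 0.12 log2 CPM in control and 4.60 ± 0.05 in C2-AKT livers). The smallest p is the one at issue here. Most of the 39 lists would have had to reach that p for any to pass, so with n = 4 the exact test could hardly pass a list. Without control replicate 5, 4 lists passed camera.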

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

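The tests of pancreatic RNA, of reads carried over, of the share of genes around ROSA26 and of sequencing depth were chosen only after the result was seen, as was every fit that uses the title endings. The splits of the libraries and the GC and length tests of the title endings were set before their results were seen.

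C2-AKT replicate 5 held 8.80% of its counts in the acinar cell list and 13.4 mean log2 CPM over that list's 2 measured genes, against 0.38 to 2.07 in the other C2-AKT libraries. All 6 islet hormone genes examined, which had no count in the control libraries, were above 10 times the limit of 3 counts in any of those libraries (Ins2 with 1753 counts, Gcg with 81), and the hepatocyte list on all counts lay 0.32 below the mean of the other 3 C2-AKT libraries (-0.32), where the 17.2% of counts in genes removed by the filter would by itself give -0.27, so pancreatic tissue or its RNA in this liver sample is a candidate explanation. In C2-AKT replicate 4, 25 genes abundant in C2-AKT replicate 5 were present at a median of 0.0191% of their level there, with an interquartile range of 0.28 on the log2 scale and a rho of 0.939 across genes, so a small share of reads carried over from C2-AKT replicate 5 may account for that trace. A trace of pancreatic RNA in the replicate 4 sample itself could give the same profile, so the check cannot tell these apart. C2-AKT replicates 2 and 3 had acinar shares of 0.000914% and 0.000962%, within the control range of 0.000747% to 0.00152%, which argues against pancreatic transcripts as a feature of the genotype. When the pancreatic RNA entered the sample was not tested.

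Bid, Mug2 and Gm10319 lie within 10 Mb of the locus that carries the construct, and 15 of 234 genes within 20 Mb of it had an unadjusted p below 0.01. Of 35 splits of the 8 libraries, 1, the real one, gave 15 such genes and the highest other gave 8. The region was examined after Bid, Mug2 and Gm10319 had been called in the real split, which favours that split. First of 35 is also the strongest outcome the splits allow, so chance is not excluded. Pancreatic RNA is argued against, because without C2-AKT replicate 5 the region still stood apart (Fisher's exact p = 1.53e-05). Shared reads among murinoglobulin genes are not the whole cause, because without those genes 5.24% of the region remained. Of 487 other windows of 40 Mb, 0 reached that share (highest 4.48%, on chromosome 3). These windows overlap one another, so they are not 487 separate comparisons. DNA of another strain carried along with the ROSA26 allele, or the insertion acting on its surroundings, may therefore account for part of the lower calls. Neither was compared with an effect of the C2-AKT protein, which travels with the same allele and stays open as untested.

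The 1616 genes that differed between libraries with no title ending and those ending in "_1" comprised 312 higher and 1304 lower in the libraries with no ending. Sequencing depth and transcript length are argued against, since 2 of the 2 libraries with no ending had totals inside the range of the others and 109% as many calls were left after correction in length bins. GC content may account for part of the pattern: rho between transcript GC and the log2 fold change was -0.497 across 14620 genes, which are not independent, and 48.7% as many calls were left after correction in GC bins, just under the limit of 50% set beforehand (816 against 1675 among the genes with a GC value). Of the 1675 genes, 577 were called both before and after that correction, in 20 bins of mean transcript GC, and whether a finer correction would end those calls was not tested. The genotype calls numbered 5 after the GC correction and 3 after the length correction, and no biological explanation was tested, since the labels do not say what the endings mean.

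Over 128 groups of 4 libraries tested, 5 held a library far from the rest of its group, where chance gives about 6.4 (1 in 20 groups). Beside the acinar list these were Depp1 in control replicate 2 at 44.7 CPM (the others 15.4 to 18.0), the acute phase list in C2-AKT replicate 5 at 7.67 mean log2 CPM (6.70 to 6.84), the growth hormone and male-biased list in control replicate 4 at 7.73 (7.21 to 7.23) and the adipocyte list in control replicate 3 at 3.85 (2.89 to 2.98).

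Other splits of the 8 libraries into 4 and 4 were counted for each result. For the 4 called genes, 1 of 35 splits, the real one, gave 4 calls and the highest other gave 2. First of 35 is the strongest outcome the splits allow, and several results were put through them, so chance is not excluded. Mug2 and Gm10319 are murinoglobulin copies that can share reads, so the 4 calls are not independent. For the number of lists past the threshold chance cannot be excluded, since 14 of 35 splits gave at least the real 11 and the highest other gave 15; 3 of the 14 put both libraries with no title ending in one group. For the difference in mean of the cholesterol synthesis list chance cannot be excluded either, since 3 of 35 splits, the real one included, gave at least the real 0.96 and the highest other gave 1.03. The list's exact permutation p of 0.0857 is the same test.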

How the results depend on the processing

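The fits with the title ending, and the exact permutation test of lists, were chosen only after the data were seen. Under the 23 alternatives Mug2, Bid and Pim1 kept their negative direction, and Gm10319 was called in all of them. Mug2 lost its call in 1 (adjusted p = 0.0706 without control replicate 2), Bid in 4 and Pim1 in 15, with adjusted p up to 0.0706, 0.137 and 0.176. Genes higher in C2-AKT livers numbered 0 in edgeR (805 genes in either direction at an unadjusted p below 0.05), but 29 with DESeq2 and 1 with library sizes that leave out the 20 most abundant genes. They numbered 1 with the title ending as a term, with or without C2-AKT replicate 5. With 1 library left out they numbered 0 to 3: 3 without C2-AKT replicate 3 and 1 without control replicate 4, control replicate 5, C2-AKT replicate 2 or C2-AKT replicate 4. Genes lower numbered 4, but 27 with DESeq2, 17 among titles ending in "_1", and from 1 (without control replicate 2) to 16 (without C2-AKT replicate 2) with 1 library left out. Many of the 17 and of the 16 were Mup copies, between which reads can be shared out. The cause of these changes in number was not tested. The 11 gene lists past the threshold became 0 with an estimated correlation and with fry's directional test, which by construction allow for correlation between genes. Yet the estimated correlation was only 0.0125 for the lipid droplet list and -0.0164 for the circadian clock list, against the preset 0.01. Camera's unadjusted p still rose, from 7.15e-05 to 0.00805 and from 0.00397 to 0.0203. Correlation between members therefore does not account for the loss of these lists, and the cause was not tested. The 11 lists also became 0 with the exact permutation test. Its smallest possible p of 0.0286 passes adjustment only if most of the 39 lists reach it, so that 0 was largely set by the group size. The number of lists past the threshold was 17 with the title ending as a term, with or without C2-AKT replicate 5. With 1 library left out it ranged from 4 (without control replicate 5) to 14 (without control replicate 3). The sign of Akt1, which was never called, turned with library totals (-0.0086), limma on log2(FPKM + 1) (-0.0026) and log2(FPKM + 0.1) (-0.0027), the title ending as a term (-0.061, and -0.061 without C2-AKT replicate 5) and titles ending in "_1" (-0.075). With 1 library left out it ranged from -0.10 to 0.17. The cause was not tested. The ribosomal protein list ranged from -0.13 to -0.0011 with 1 library left out, where camera's direction turned without control replicate 5 and without C2-AKT replicate 4. The replicate block gave 0 genes higher and 4 lower in edgeR (693 at an unadjusted p below 0.05), 3 of them among the 4 called without it, and 12 lists. With the block Cxcl1 was called and Bid was not. No pairing by the shared numbers was seen (correlations of -0.13, -0.02, 0.07 and -0.06, and 0 libraries best matched to their own number). Control replicate 5 matched C2-AKT replicate 2 best, the other library with no title ending. Differences that go with the endings, and the pancreatic transcripts, could hide a pairing, so this check cannot exclude one. No scaling moved the median of all genes beyond 0.05. At 51.4 to 63.8 M counts per library depth limits genes of a few counts, such as Gt(ROSA)26Sor in C2-AKT livers. What limits the other genes was not tested. In the simulation 74 of 100 2-fold changes were recovered, but 200 genes were changed there and 186 were called. With only 4 calls the adjusted threshold asks for a smaller unadjusted p, so that share is not the recovery in the real data.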

Other observations

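The lists in this part, and all of their tests, were chosen only after the values of some of their members were seen.

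The MHC class II genes, which present antigen, all had higher means in C2-AKT livers (7 of 7), with a difference in mean log2 CPM of 0.48 between groups. H2-Aa stood at 18.3 ± 1.84 CPM in control and 25.6 ± 2.01 CPM in C2-AKT livers (SD, n = 4; log2 fold change 0.48 ± 0.10, edgeR adjusted p = 0.441), without overlap between groups, and was called by DESeq2. Ciita, the transactivator of these genes, had a log2 fold change of 0.66 ± 0.31, and Cd74, which is also in the B and plasma cell list, 0.51 ± 0.31. The list's exact permutation p was 0.0571. Counted as splits, the same test gave a difference as large in 2 of 35, the real one included (highest other 0.56), so chance cannot be excluded. Of the marker lists of antigen-presenting cells, B and plasma cells passed camera in the same direction (adjusted p = 0.0104), but not with an estimated correlation (0.318), nor without control replicate 5 (0.0570), C2-AKT replicate 2 (0.0741) or C2-AKT replicate 5 (0.0529). Kupffer cells and macrophages had 10 of 12 members lower (median -0.09, camera adjusted p = 0.265, and 0.0219 without control replicate 4), and monocytes and lipid-associated macrophages had 5 of 10 higher (0.372).

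The inducible heat shock genes Hspa1a and Hspa1b had log2 fold changes of 1.12 ± 0.25 and 1.17 ± 0.23, and Dnajb1 0.66 ± 0.12, each without overlap between groups (n = 4) and without passing in edgeR (adjusted p = 0.512, 0.281 and 0.266). The hypothesis that heat shock genes were higher as a group was not borne out by the rest of the list: 6 of 14 genes were higher, and Hsph1, Hsp90aa1 and Hspb1 had log2 fold changes of -0.10, -0.18 and -0.77. Of the 35 splits, 7, the real one included, gave a difference in mean as large as the real 0.15 (highest other 0.22). The exact permutation p of 0.200 is the same test.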
